A study of Mus musculus with 8 samples.

How the data were processed

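RNA from hand-picked pancreatic islets of 12-week-old C57BL/6 mice, freed with collagenase (1 mg/ml) and purified on a density gradient, was sequenced in 8 libraries made from 1 µg of total RNA each, per the labels' protocols. Groups were taken from the labelled genotype, with 4 libraries of ob/+ and 4 of ob/ob. The labels do not say that each library is a separate mouse, so p-values measure the spread between these libraries, which may be in part technical.

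The deposited values are FPKM, a unit inferred from the values and named neither in the labels nor in the file headers: they have 2 decimals, their sums per library differ, and low values multiplied by transcript length tend towards whole multiples of 1 step per library, though not exactly (mean cosine of their phase 0.575 to 0.636, where 1 is an exact fit). Trimmomatic 0.36, DESeq2 1.20.0 and the builds mm10 and GRCm38 are named in the submitters' processing notes, without a role; the aligner and the quantifier are not given in the sources used here. The authors listed 20715 genes, of which 3314, Lep among them, had no value in any library, and 12 carried names that a spreadsheet had turned into dates. Values relative to the library total mean that a larger share of insulin or acinar transcripts lowers the values of other genes. Relative depth is a rough estimate from these steps, and absolute depth is unknown, so no counting intervals are given. FPKM also carries no counts, which is why the planned count tests were replaced by the planned test for normalized values.

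Genes at 1 FPKM or more in at least 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust, statmod 1.5.0), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes; ratios given as fold are of mean FPKM. On simulated data with known answers the test called 40.4% of genes changed by 0.5 on the log2 scale. It called 91.9% of those changed by 1, with 99 tested genes of each size. Of 137 calls among 11621 genes 4.4% were false, and none of 30 lists was called. The simulated noise was independent between genes and libraries, without shared shifts. In the real libraries, splits into 4 and 4 that mixed the genotypes called up to 2144 genes and 15 lists. Splits that mix the genotypes unequally hold part of the genotype difference, so those calls are not known to be false. As the simulation held no shared shifts, its rates of false calls do not carry over to these data.

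A set of 35 gene lists, the design, the alternatives and the naming rule were fixed before the data were examined. Each list of at least 5 tested members (30 lists) was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. Camera at an estimated correlation and fry were run beside it. A list that camera calls higher or lower is so against the other tested genes, not against no change. Camera at the preset correlation called 14 lists (8 higher, 6 lower) and at the estimated correlation 0, with 1 list at an unadjusted p under 0.05. Fry called 7 lists as moving on balance one way and 26 as changing in either direction. The 7 were alpha cell, delta and PP cell and dedifferentiation markers, genes normally low in beta cells, protein folding, glycolysis and oxidative stress defence. Fry did not call the other lists that camera called as moving on balance one way. Named genes were Lep and Lepr, 14 islet genes set in advance, the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 1 FPKM (without predicted genes and acinar genes), and up to 4 members of each list with the smallest p; other genes named were chosen after their values were seen. Some genes that this rule or a list takes are not reported here by name; they stayed in the gene counts and list tests and were left out of the test for libraries far from their group. Summed FPKM, the shares of insulin, of the 10 most abundant genes and of acinar genes, and the number of genes at 1 FPKM were compared by exact two-sided permutation tests over 70 assignments, with SciPy 1.17.1. No libraries were duplicates: the correlation of log2 values was 0.978 to 0.993 within and 0.955 to 0.965 between groups, and at most 2.6% of values were identical.

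Gene positions come from the GENCODE annotation of GRCm38, in which 96.7% of listed symbols had 1 match. Alternatives covered the library scaling, the low-value filter, the pseudocount, a replicate block, an acinar covariate and leaving out each library; others were added after the data were seen.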

Results

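Islet RNA was sequenced from 12-week-old C57BL/6 mice, with 4 libraries from ob/+ mice and 4 from ob/ob mice. The ob mutation lies in Lep, the gene of leptin, the fat cell hormone that restrains food intake, and mice with 2 mutant copies are known to become obese and insulin resistant. Islets are the endocrine clusters of the pancreas, in which beta cells make insulin, alpha cells glucagon, delta cells somatostatin and PP cells pancreatic polypeptide. Values were in FPKM, and between 11363 and 11883 genes per library reached 1 FPKM. Summed FPKM ran from 820968 to 880570 in ob/+ and from 920734 to 1004230 in ob/ob. Absolute depth is unknown, and the relative depth, roughly estimated from low values, ran from 0.976 to 1.03 across the 8 libraries.

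The comparison asks which islet transcripts differ between ob/ob and ob/+ mice. Lep itself (GRCm38 chromosome 6, 29060220 to 29073877, plus strand) was listed without a value in each of the 8 libraries, so the files hold no check of the genotype by its own transcript. Lepr, the leptin receptor, was at 0.905 ± 0.338 FPKM (SD, n = 4) in ob/ob and 0.948 ± 0.098 (SD, n = 4) in ob/+ and lay below the expression filter.

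In ob/ob islets Aldh1a3, an aldehyde dehydrogenase known as a marker of failing beta cells, rose from 0.767 ± 0.319 to 62.6 ± 3.23 FPKM (SD, n = 4 each), 81.5-fold. Somatostatin (Sst) fell from 5640 ± 297 to 1238 ± 190 FPKM, glucagon (Gcg) from 26865 ± 3256 to 8424 ± 1241 and pancreatic polypeptide (Ppy) from 6357 ± 1547 to 2178 ± 663 (SD, n = 4 each). The beta cell hormone amylin (Iapp) rose from 28021 ± 2324 to 47755 ± 3059. The beta cell genes Mafa, a transcription factor of mature beta cells, and Slc2a2, the glucose transporter GLUT2, fell to 54.9 ± 9.18 from 122 ± 12.6 FPKM and to 86.6 ± 10.3 from 213 ± 27.6 (SD, n = 4 each). Of 27 tested genes listed for protein folding in the endoplasmic reticulum 9 rose and none fell, and of 17 tested genes listed for glycolysis 9 fell and none rose.

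Across 11747 tested genes, limma with Benjamini-Hochberg adjustment called 2208 changed, 965 higher and 1243 lower in ob/ob, and 292 of them by a log2 fold change of 1 or more in size (137 higher, 155 lower). The number and balance of the calls moved with the library scaling: 43.7% of the calls were higher with the deposited scaling, 67.3% with the 10 most abundant genes left out of it and 6.3% with the acinar genes left out of it. These scalings shifted the median log2 fold change of all tested genes by 0.10 and by -0.25. Under all 5 scalings tried, 1071 genes kept their call and direction (470 higher, 601 lower). Signs turned under at least 1 scaling for 31 of the 2208 genes, none of them with a log2 fold change of 0.5 or more in size. Leaving out ob/+ 4 gave 4832 changed genes and leaving out ob/+ 1 gave 1434. The groups did not overlap for 20.5% of tested genes, where chance gives 2.9%.

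**Figure D1:**
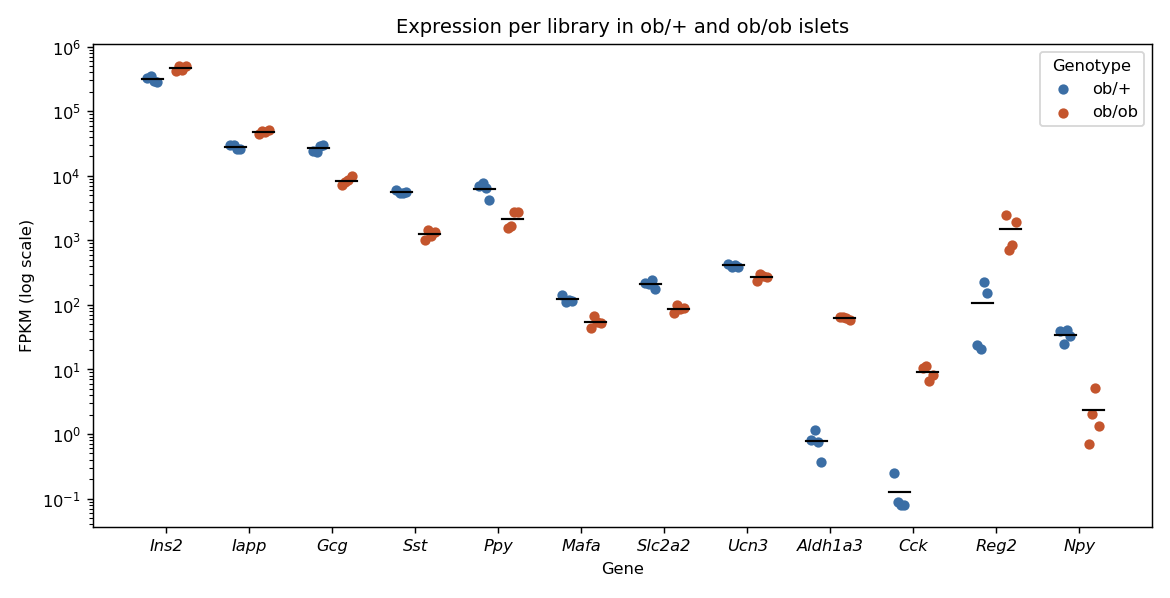
FPKM (log axis) of 12 genes in each library; points are libraries, 4 per genotype, and black lines are group means. Each ob/ob library lies on the same side of the ob/+ libraries for every gene drawn, with Aldh1a3 between 58.3 and 65.5 FPKM in ob/ob against 0.37 to 1.15 in ob/+; the call of Ins2 ended with median centring, with upper-quartile scaling and with the acinar genes left out of the scaling.

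Islet hormones and secretory granule proteins held calls in both directions. Of 20 tested members 9 rose and 5 fell (11 and 5 when adjusted over the list alone). The granule proteins chromogranin B (Chgb, log2 fold change 1.16 ± 0.10 SE, adjusted p = 4.35e-08) and Vgf (2.19 ± 0.14 SE, adjusted p = 8.94e-10) rose. Insulin 2 (Ins2, chromosome 7, 142678656 to 142743381) rose from 314288 ± 33897 to 464014 ± 42580 FPKM (SD, n = 4 each; adjusted p = 5.40e-05). The log2 fold change of Ins2 was 0.56, and its call ended at a change of 0.63 with median centring (adjusted p = 0.166), 0.62 with upper-quartile scaling (0.208) and 0.26 with the acinar genes left out of the scaling (0.0544). It also ended without the robust option of eBayes (adjusted p = 0.456) and with a fold threshold of 1.5. Ins1 was at 122821 ± 26551 against 101918 ± 10841 FPKM (adjusted p = 0.216) and changed sign under 1 scaling. The 4 hormones of other islet cells, Gcg, Sst, Ppy and peptide YY (Pyy, -1.18 ± 0.19 SE), fell, with the zinc transporter Slc30a8. Camera called the list higher (adjusted p = 0.0193; adjusted p = 0.895 with an estimated correlation). Its median turned to -0.02 with the acinar genes left out of the scaling, and the call ended with the 10 most abundant genes left out (adjusted p = 0.0641). Ins1 and Ins2 are near-identical, so their separate values are uncertain. Together they took 60.7% ± 3.72 of summed FPKM in ob/ob and 48.8% ± 5.31 in ob/+ (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allow; 0.0476 after adjustment over 5 measures). The 10 most abundant genes took 70.8% ± 2.26 and 64.1% ± 1.18 (exact permutation p = 0.0286).

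Markers of alpha, delta and PP cells were lower in ob/ob. Of 11 tested alpha cell markers 7 fell and 2 rose (the same counts when adjusted over the list alone). Of 6 tested delta and PP cell markers 5 fell and 1 rose (also when adjusted over the list alone). Gcg (chromosome 2, 62474530 to 62483650) fell by 1.68 ± 0.10 on the log2 scale (SE, adjusted p = 1.27e-09). The alpha cell transcription factor Irx1 (-1.55 ± 0.13 SE) fell by a similar amount. Sst (chromosome 16, 23889573 to 23890958) fell by 2.20 ± 0.09 (SE, adjusted p = 1.37e-13), its delta cell regulator Hhex by 1.10 ± 0.17 and the retinol carrier Rbp4 by 2.30 ± 0.11. The alpha list members that rose were the vitamin D carrier Gc (2.25 ± 0.14 SE) and transthyretin (Ttr, 0.32 ± 0.09). Camera called the delta and PP list lower (adjusted p = 0.000195; adjusted p = 0.862 with an estimated correlation) under each of 21 alternatives. The alpha list was called lower as well (adjusted p = 0.00558; adjusted p = 0.862 with an estimated correlation). That call ended without ob/+ 4 (adjusted p = 0.108) or with the acinar genes left out of the scaling (0.193). It also ended without both ob/+ 4 and ob/ob 1 (camera adjusted p = 0.065), the library richest in acinar transcripts of each genotype. The medians of both lists stayed below -1 under the 5 scalings.

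Beta cell identity genes divided by gene. Of 18 tested beta cell transcription factors 4 fell and 1 rose (5 and 1 when adjusted over the list alone). Mafa fell by 1.15 ± 0.11 on the log2 scale (SE, adjusted p = 4.12e-08) and Neurod1 by 0.62 ± 0.10, while Rfx6 rose by 0.67 ± 0.10. Pdx1 (68.8 ± 9.57 against 78.5 ± 13.3 FPKM, adjusted p = 0.336) and Nkx6-1 (134 ± 21.0 against 148 ± 34.4, adjusted p = 0.726; SD, n = 4 each) did not pass the test. Without ob/+ 4 Pdx1 and Nkx6-1 passed it as lower (adjusted p = 0.0196 and 0.0392). Of 21 tested genes of glucose sensing and beta cell function 5 fell and none rose, also when adjusted over the list alone. They were Slc2a2 (-1.29 ± 0.10 SE, adjusted p = 2.09e-09), the cation channel Trpm5 (-2.40 ± 0.12), urocortin 3 (Ucn3, -0.60 ± 0.09), pyruvate carboxylase (Pcx, -0.65 ± 0.11) and Slc30a8. The transcription factor list was not called by camera (adjusted p = 0.223). The glucose sensing list was called lower (adjusted p = 0.0438; adjusted p = 0.895 with an estimated correlation). This call held in 11 of 21 alternatives and ended without ob/+ 3 (adjusted p = 0.0585), ob/ob 1 (0.0575) or ob/ob 4 (0.0559).

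Among 8 tested markers of beta cell dedifferentiation 3 rose and 2 fell, also when adjusted over the list alone. Aldh1a3 rose by 5.19 ± 0.13 on the log2 scale (SE, adjusted p = 2.26e-19). Of the gut hormone genes, cholecystokinin (Cck) rose from 0.125 ± 0.083 to 9.18 ± 2.20 FPKM and gastrin (Gast) from 0.495 ± 0.166 to 5.28 ± 0.674 (SD, n = 4 each). Fev fell by 1.57 ± 0.13, and Gata6 fell. Neurog3, Myc and Cd81 did not pass. Camera called the list higher (adjusted p = 0.0418; adjusted p = 0.862 with an estimated correlation) in 8 of 20 alternatives. Without ob/+ 1 and ob/+ 2 its adjusted p was 0.0549 and 0.0721, and without ob/ob 1, 2, 3 and 4 it was 0.925, 0.870, 0.934 and 0.985. With 3 ob/ob libraries Cck and Gast no longer met the filter of 1 FPKM in 4 libraries. Of 15 tested genes that are normally low in beta cells 4 fell and none rose (6 fell when adjusted over the list alone), among them Acot7 (-1.58 ± 0.14 SE) and Ndrg2 (-0.90 ± 0.13 SE). This list was called lower (adjusted p = 0.00660; adjusted p = 0.862 with an estimated correlation), but in 15 of 21 alternatives only, and not without ob/+ 4 (adjusted p = 0.332).

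Protein folding genes of the endoplasmic reticulum rose where they passed the test. Of 27 tested members 9 rose and none fell (also 9 when adjusted over the list alone). Derl3, a factor of protein disposal, was at 60.4 ± 3.50 against 19.9 ± 3.34 FPKM (SD, n = 4 each; log2 fold change 1.57 ± 0.11 SE, adjusted p = 1.93e-10). Creld2 (1.17 ± 0.10 SE), the co-chaperone Dnajc3 (0.80 ± 0.11) and the disulfide isomerase Pdia6 (0.68 ± 0.11) rose as well. Camera called the list higher (adjusted p = 2.78e-07; adjusted p = 0.862 with an estimated correlation) under each of 21 alternatives. Its median of 0.23 turned to -0.07 with the acinar genes left out of the scaling, with 5 members higher and 4 lower. In the integrated stress response list 1 of 18 tested members rose and 2 fell, also when adjusted over the list alone. Ddit4 rose by 1.08 ± 0.19, and Atf5 (-1.09 ± 0.15 SE) and Eif4ebp1 fell (camera adjusted p = 0.669).

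Genes of glycolysis fell where they passed the test. Of 17 tested members 9 fell and none rose, also when adjusted over the list alone. Aldolase A (Aldoa) was at 164 ± 8.32 against 247 ± 20.1 FPKM (SD, n = 4 each; -0.58 ± 0.09 SE, adjusted p = 1.85e-05). The phosphofructokinases Pfkp (-0.65 ± 0.12 SE) and Pfkl (-0.61 ± 0.12) and hexokinase 1 (Hk1, -0.84 ± 0.13) fell too. Camera called the list lower (adjusted p = 0.00517; adjusted p = 0.862 with an estimated correlation) under each of 21 alternatives. Of 53 tested respiratory chain genes 7 rose and 2 fell (7 and 1 when adjusted over the list alone), led by Ndufa1 (1.11 ± 0.09 SE). Camera called them higher (adjusted p = 0.0438; adjusted p = 0.895 with an estimated correlation) in 12 of 21 alternatives. The call ended without ob/+ 1 (adjusted p = 0.0549), ob/+ 2 (0.093), ob/+ 3 (0.366) or ob/ob 4 (0.204). With the acinar genes left out of the scaling 35 members were lower and 2 higher. Among 11 tested glucose-responsive targets of ChREBP 4 rose and 1 fell, also when adjusted over the list alone, led by Arrdc4 (1.09 ± 0.13 SE). The ChREBP list was called higher by camera (adjusted p = 0.0314; adjusted p = 0.862 with an estimated correlation), but not without ob/+ 2 (adjusted p = 0.076) or with median centring (0.0525). With the acinar genes left out of the scaling the list's median turned from 0.24 to -0.03.

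Lipid, redox, hypoxia and signalling lists were not called by camera. Fatty acid synthesis had 3 higher and 3 lower of 17 tested (3 and 4 when adjusted over the list alone; Dgat2 0.67 ± 0.13 SE, Fads2 -0.56 ± 0.12 SE; camera adjusted p = 0.844). Cholesterol genes had 1 higher and 3 lower of 23 (1 and 4 when adjusted over the list alone; camera adjusted p = 0.815), and fatty acid oxidation 1 and 1 of 19, the same when adjusted over the list alone (camera adjusted p = 0.366). The pyruvate dehydrogenase kinase Pdk4 was at 2.40 ± 0.491 against 9.85 ± 3.28 FPKM (SD, n = 4 each; -1.64 ± 0.18 SE, adjusted p = 6.48e-06). In oxidative stress defence 7 of 20 tested members fell and 2 rose (7 and 3 when adjusted over the list alone). Camera did not call this list (adjusted p = 0.375), but fry called it as moving on balance one way (adjusted p = 0.00791). The metallothioneins Mt1 (146 ± 48.0 against 637 ± 138 FPKM) and Mt2 (72.7 ± 30.5 against 341 ± 88.4; SD, n = 4 each) fell by most. Hypoxia genes had 3 lower of 13 (5 when adjusted over the list alone; camera adjusted p = 0.176). Insulin, leptin and cytokine signalling had 4 lower and 1 higher of 18, also when adjusted over the list alone (camera adjusted p = 0.275). Its adaptor Grb10 fell by 0.99 ± 0.12, and Socs3 rose by 0.70 ± 0.15. Insulin granule exocytosis had 6 lower and 4 higher of 19 (7 and 4 when adjusted over the list alone; camera adjusted p = 0.557). Syntaxin 1A (Stx1a, -0.94 ± 0.12 SE) fell and synaptotagmin 5 (Syt5, 0.74 ± 0.11 SE) rose. Prolactin and serotonin genes of islet expansion had 2 higher of 7 (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.648).

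Most proliferation genes did not pass the test one by one. Of 27 tested members 2 rose, the nucleotide reductase subunit Rrm2 (0.92 ± 0.13 SE) and E2f1 (0.71 ± 0.12 SE), and cyclin D2 (Ccnd2) fell, also when adjusted over the list alone. The call of Ccnd2 was lost on leaving out any library but ob/+ 4 (adjusted p = 0.0507 to 0.0708). Mki67, a marker of cycling cells, was at 1.31 ± 0.247 against 1.02 ± 0.574 FPKM (SD, n = 4 each; adjusted p = 0.377). Camera called the list higher (adjusted p = 0.0155; adjusted p = 0.895 with an estimated correlation), but not without ob/+ 1 (adjusted p = 0.0979), and its median of 0.14 turned to -0.06 with the acinar genes left out of the scaling. Cell cycle inhibitors had 2 higher and 3 lower of 10 tested (3 and 3 when adjusted over the list alone; camera adjusted p = 0.557).

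Immediate early genes, which respond within minutes to stimulation or handling of cells, were called higher as a list of 15 by camera (adjusted p = 0.000600; adjusted p = 0.862 with an estimated correlation). Of its members 2 passed the test (1 when adjusted over the list alone). Fos was at 77.9 ± 68.1 against 5.84 ± 1.80 FPKM (SD, n = 4 each; adjusted p = 0.0425), and its call was lost on leaving out any library but ob/ob 4 (adjusted p = 0.0542 to 0.117). Of 16 tested interferon-stimulated genes 2 rose (1 when adjusted over the list alone), led by Usp18 (1.04 ± 0.13 SE). As a list they were called higher by camera (adjusted p = 0.00604; adjusted p = 0.895 with an estimated correlation), but not without ob/ob 2 (adjusted p = 0.21). Its median of 0.19 turned to -0.03 with the acinar genes left out of the scaling. None of 9 NF-kB and chemokine genes (camera adjusted p = 0.400), 18 macrophage markers (0.669) or 2 lymphocyte markers passed the limma test, also when adjusted over the list alone. Without both ob/+ 4 and ob/ob 1 camera called the macrophage list higher than the other tested genes (adjusted p = 0.0112). The median log2 fold change of all tested genes was -0.13 in that fit. With the acinar genes left out of the scaling that median was -0.33. There the macrophage markers Cd14 (limma adjusted p = 0.00418), Csf1r (0.00821) and Cx3cr1 (0.0106) passed as lower.

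Markers of the other cells of an islet preparation also differed. Acinar cells, the enzyme-making cells around the islets, gave 14.1% ± 7.76 of summed FPKM in ob/+, with ob/+ 4 at 25.1%, and 6.78% ± 3.32 in ob/ob (SD, n = 4; exact permutation p = 0.0857). Of 33 tested acinar markers 1 rose (Prss1) and 1 fell (Cela3a), also when adjusted over the list alone. Camera called the list lower (adjusted p = 0.0205; adjusted p = 0.895 with an estimated correlation), but not without ob/+ 4 (adjusted p = 0.574), ob/ob 2 (0.21) or ob/ob 3 (0.0837). Trypsin and amylase genes are close paralogs, so their separate values are uncertain. Of 11 tested duct markers 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.276; 0.0371 without ob/+ 4). None of 14 endothelial markers passed, also when adjusted over the list alone (camera adjusted p = 0.984). Among 16 tested fibroblast, stellate cell and pericyte markers 5 fell and 2 rose (8 and 3 when adjusted over the list alone). The collagens Col1a1 (-1.45 ± 0.21 SE) and Col1a2 (-1.02 ± 0.14 SE) fell and the pericyte marker Rgs5 (0.62 ± 0.10 SE) rose. Camera did not call the list (adjusted p = 0.118) except, as lower, in 5 of 21 alternatives, among them without ob/+ 2 (adjusted p = 0.0371), ob/+ 3 (0.0335) or ob/ob 3 (0.0135). Of 3 tested Schwann cell markers 2 fell, Sox10 among them (2 lower and 1 higher when adjusted over the list alone). Of 3 adipocyte markers lipoprotein lipase (Lpl, 5.09 ± 1.56 against 25.1 ± 2.62 FPKM; SD, n = 4 each) and Pparg fell, also when adjusted over the list alone. Of 4 hemoglobin genes 3 rose (4 when adjusted over the list alone), with Hbb-bs at 207 ± 132 against 50.3 ± 12.3 FPKM (SD, n = 4 each; adjusted p = 0.0321). Hemoglobin genes are close paralogs, and none of the 3 calls held on leaving out each library in turn. None of 4 Y-linked genes passed, also when adjusted over the list alone. In the prolactin, duct and endothelial lists the median, the mean and the camera direction did not share a sign.

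**Figure D2:**
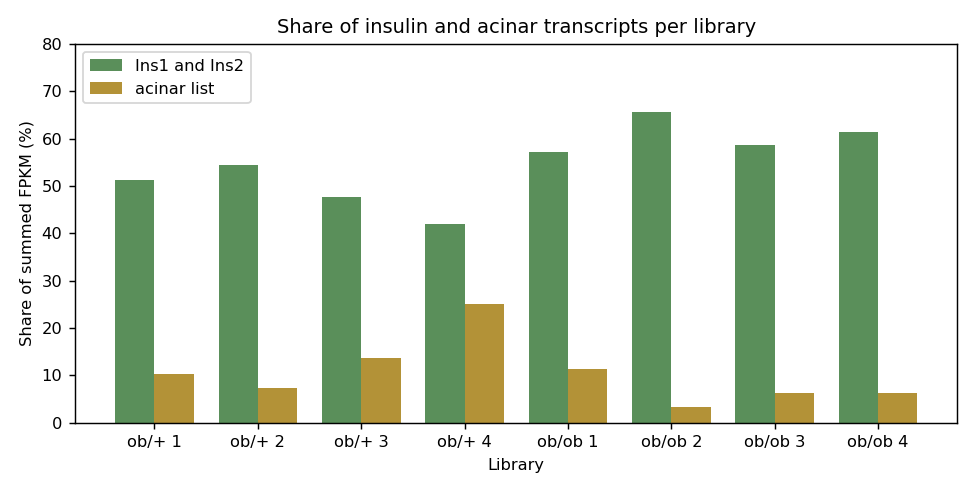
Share of summed FPKM (%) taken by Ins1 and Ins2 and by the acinar list in each library. Insulin took 57.1% to 65.6% in ob/ob and 42.0% to 54.3% in ob/+, and acinar transcripts reached 25.1% in ob/+ 4.

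The largest rises that passed the naming rule were those of Aldh1a3, Reg3a, Reg2, Reg3g, the thyroxine carrier Serpina7, Cck, Fos, C1qtnf1, Ankrd34b and the guanylate cyclase Gucy2c. The Reg genes, which encode secreted lectin-like proteins of the pancreas and gut, varied widely between libraries. Reg2 was at 1480.3 ± 839 against 106 ± 102 FPKM (SD, n = 4 each; adjusted p = 0.0262). Reg3a was at 150 ± 104 against 7.81 ± 9.88 (adjusted p = 0.0310) and Reg3g at 56.1 ± 35.6 against 2.96 ± 2.94 (SD, n = 4 each; adjusted p = 0.0119). The call of Reg2 was lost on leaving out ob/+ 1, ob/+ 2 or any ob/ob library (adjusted p = 0.0510 to 0.0798). That of Reg3a was lost on leaving out ob/+ 1, ob/+ 2, ob/ob 1, ob/ob 2 or ob/ob 4 (adjusted p = 0.0689 to 0.0925), and that of Reg3g held on leaving out each library. Reg genes are close paralogs, so their separate values are uncertain. Serpina7 rose from 7.46 ± 3.98 to 74.0 ± 13.5 FPKM and C1qtnf1 from 1.12 ± 0.078 to 15.1 ± 0.682 (SD, n = 4 each). The largest falls were those of Npy, the neuropeptide Y gene (2.33 ± 2.0 against 34.4 ± 6.92 FPKM; SD, n = 4 each; -3.56 ± 0.42 SE, adjusted p = 0.00157), vasoactive intestinal peptide (Vip, -3.13 ± 0.49 SE), Nnat (-2.69 ± 0.18), mesothelin (Msln, -2.48 ± 0.19), Trpm5, the neurofilament protein peripherin (Prph, -2.31 ± 0.16), Rbp4, Cyp4f39, T2 and Mt2. Directions of these 20 genes held under the 5 scalings.

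**Figure D3:**
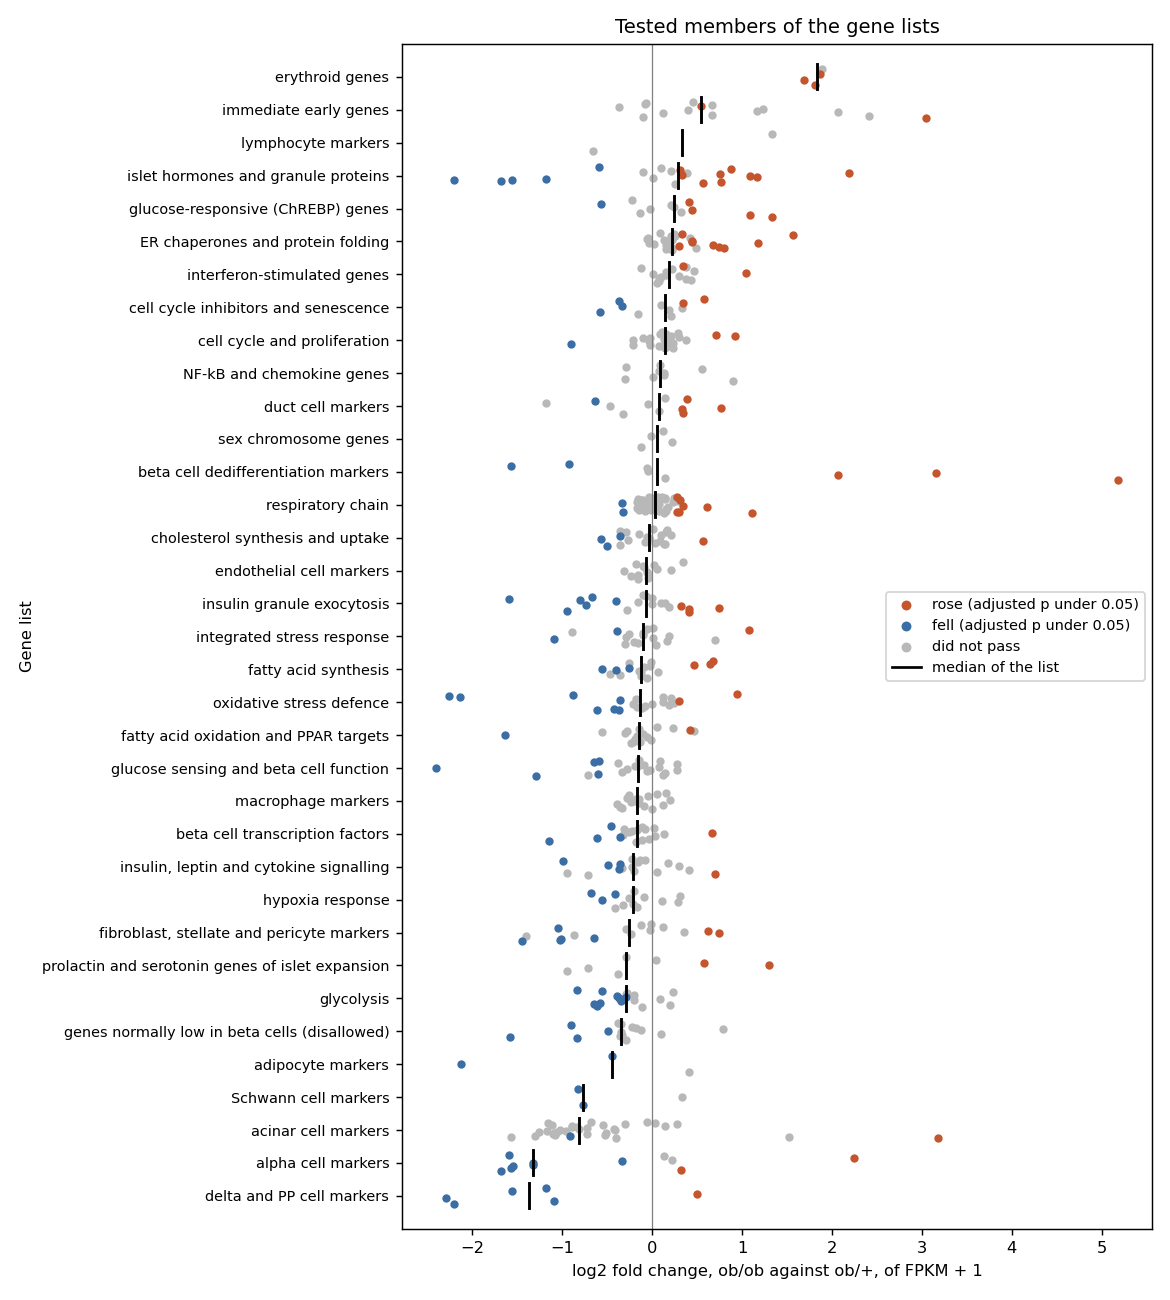
Log2 fold change (ob/ob against ob/+) of each tested member of the 35 gene lists; points are genes, coloured where they rose or fell with adjusted p under 0.05, and black lines are list medians. The delta and PP list (median -1.37) and the alpha list (median -1.32) lie lowest; several medians near 0 change sign with the acinar genes left out of the scaling.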

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

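No result here had its test chosen after the values were seen, since the rule for a library far from its group was set in advance. It was applied to 153 named genes and 5 library measures in 316 groups of 4 libraries; 20 groups held a library whose gap to the nearest other was large against the range of the group, where chance gives about 1 in 20 groups, or 15.8.

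The library ob/+ 4, the richest in acinar transcripts, stood apart in 6 of them. It was lowest for cyclin D2 (Ccnd2, 87.0 FPKM, the others 161 to 171), Sytl4 (64.5 FPKM) and Hif1a (12.3 FPKM), and highest for Prss1 (2.18 FPKM, the others 0.44 to 0.66), Col6a1 (5.12 FPKM) and Cxcl16 (3.09 FPKM). Of the other ob/+ libraries, ob/+ 1 was highest for Sst (6082 FPKM, the others 5440 to 5541) and for Cck (0.25 FPKM), ob/+ 2 was lowest for Rbp4 (98.2 FPKM), and ob/+ 3 was highest for Slc2a1 (4.59 FPKM) and lowest for Sox10 (1.10 FPKM, the others at 1.16).

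Among ob/ob libraries, ob/ob 3 was highest for the hemoglobin gene Hba-a1 (641 FPKM, the others 156 to 237). The library ob/ob 1 was highest for Mt1 (218 FPKM, the others 117 to 126) and Fads2 (6.50 FPKM) and lowest for Rbp4 (16.5 FPKM). Usp18 was highest in ob/ob 2 (22.1 FPKM), and ob/ob 4 was highest for Dnajc3 (119 FPKM) and Thrsp (5.36 FPKM) and lowest for Akt2 (19.4 FPKM) and Higd1a (0.68 FPKM).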

How the results depend on the processing

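Upper-quartile scaling, acinar genes left out of the scaling, a fold threshold of 1.5 and a filter of 5 FPKM were added after the data were seen. So were eBayes without robust, the immediate early covariate and leaving out both ob/+ 4 and ob/ob 1. These are the libraries with the largest acinar share of their genotype. No gene called in the comparison and under an alternative had the opposite sign there, and no named gene reversed. The 5 library measures kept their side of the threshold or moved by less than 1 SD. With any library left out, too few assignments remain for their exact permutation test to pass the threshold. For those alternatives the test therefore cannot decide whether a difference in these measures held, and only the size of the move is informative. The 2208 changed genes (965 higher, 1243 lower) became 3429 with median centring (1823 higher), 3454 with the acinar covariate (2583 lower) and 3465 with upper-quartile scaling (1640 higher). They became 7486 with the acinar genes left out of the scaling (475 higher, 7011 lower) and 232 with the fold threshold (110 higher, 122 lower). They became 876 with the immediate early covariate (375 higher, 501 lower) and 4000 (2988 lower) without both ob/+ 4 and ob/ob 1. Lower genes were 621 with the 10 most abundant genes left out of the scaling and 803 with the filter of 5 FPKM, which tests fewer genes. Leaving out 1 library gave 1434 to 4832 changed genes, 713 to 1104 higher and 635 to 3728 lower, and 11 to 13 lists. The 14 called lists became 9 with median centring and 7 with the immediate early covariate. Camera calls held under all 21 alternatives for 3 lists (delta and PP cells, protein folding, glycolysis). They held under 17 to 20 for immediate early, hormone, interferon, alpha, proliferation and ChREBP genes, and under 8 to 15 for the rest. These counts include the fold threshold and eBayes without robust, which leave camera unchanged by construction. The immediate early covariate differs between the genotypes, so it removes part of the comparison by construction. The fold threshold demands a larger change, so it calls fewer genes by construction. With the acinar genes left out of the scaling the median log2 fold change of all tested genes moved by -0.25, towards lower calls. For the other alternatives the cause was not tested.

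Camera directions of lists turned as follows, with camera adjusted p-values. Dedifferentiation markers turned without ob/ob 1, 2 or 3 (0.870 to 0.934), for want of Cck and Gast in the test. Over all libraries left out, their adjusted p was 0.0181 to 0.985. Acinar markers turned with the acinar covariate (0.829), the acinar genes left out of the scaling (0.584) and the immediate early covariate (0.461). They also turned without ob/+ 4 (0.574), with 3.45e-06 to 0.574 over all libraries left out. Immediate early genes turned with their covariate (0.127). Macrophage markers turned with the immediate early covariate (0.0462) and without both ob/+ 4 and ob/ob 1 (0.0112). The cause was not tested for the macrophage list. Values that passed no test in either fit and turned sign are not counted as turned.

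The replicate block gave 2674 changed genes and 11 lists; calls it ended include those of Ppy, Reg2, Reg3a, Reg3g, Fos, 3 hemoglobin genes and the glucose sensing, dedifferentiation and respiratory chain lists. Same-numbered libraries had correlations of -0.22, 0.21, 0.17 and 0.12 of their deviations, and not every library correlated best with its own number, so the labels' numbers were not taken to pair the libraries. The count tools planned for count tables (edgeR with upper-quartile factors, glmTreat and a CPM filter, DESeq2 and limma-voom) do not apply to FPKM and were not run. What depth limits was not tested, as absolute depth is unknown; a simulated log2 change of 0.5 was recovered for 16 of 51 genes below the median expression and 24 of 48 above it.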

Other observations

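In this part the tests of alpha, delta and PP cell members that rose, of the endothelial median, of the acinar gap, of the Prss1 to Prss2 ratio and of larger changes and other windows around Lep were chosen after the values were seen, as were the 3 patterns and the imprinted gene list.

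Imprinted genes, expressed from the copy of 1 parent, were among the falls. Nnat, Mest (0.557 against 2.58 FPKM), Grb10 and Cdkn1c fell in ob/ob and raised the question. Of these, Mest lies within 5 Mb of Lep (chromosome 6, 30723547 to 30748465), where DNA of the strain of origin of the ob mutation may remain. Of 22 other tested imprinted genes 6 were called lower and 3 higher, or 27.3% lower against 10.5% of 11721 other genes (odds ratio 3.19; one-sided Fisher's exact p = 0.0231, across genes, which are not independent replicates). The 6 were Sgce (-1.37 ± 0.13 SE), Zim1 (-1.25 ± 0.28), Plagl1 (-1.04 ± 0.12), Rasgrf1 (-0.92 ± 0.12), Impact (-0.57 ± 0.12) and Ndn (-0.38 ± 0.11), and H13, Nap1l5 and Slc22a18 rose. The hypothesis that imprinted genes were called lower more often than others thus passed a test on genes that had not raised it. It was run with the deposited scaling alone. Calls as higher were 3 of these 22 genes, against 965 of all 11747 tested genes. The one-sided test of lower calls cannot tell a tendency to fall from more frequent calls in both directions. Stromal and neuronal markers such as Col1a1 (-1.45 ± 0.21 SE), Col1a2 (-1.02 ± 0.14) and Prph (-2.31 ± 0.16) fell alongside, as did alpha and delta cell markers, and whether the imprinted genes fell with these cell types was not tested.

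Prss1 (3.18 ± 0.25 SE, 15.7 ± 2.38 against 0.938 ± 0.834 FPKM; SD, n = 4 each) rose together with 4 trypsin-like predicted genes that lie on chromosome 6 between 40964754 and 41446145, all picked after their values were seen. They were Gm2663 (3.74 ± 0.18 SE), Gm10334 (3.50 ± 0.35), 1810009J06Rik (3.15 ± 0.19) and Gm5771 (2.56 ± 0.37). The abundant trypsin genes Prss2 (4426 ± 2158 against 6022 ± 3666 FPKM) and Try5 (3775 ± 1628 against 3447 ± 1711; SD, n = 4 each) did not pass the test, and reads of such close copies are hard to tell apart.

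Lower alpha, delta and PP cell transcripts in ob/ob were weighed against RNA from acinar cells, library scaling and a change in cell numbers. The median log2 fold change of the 12 members called lower was -1.60 with the acinar covariate and -1.45 with the 10 most abundant genes left out of the scaling, and both argue against these as the whole cause. A lower number of these cells per beta cell may account for the falls, but 3 members, Gc and Ttr among them, were called higher, which fewer cells alone would not raise. Under all 5 scalings, however, only 1 alpha list member kept its call as higher, and no delta and PP list member did. Whether fewer cells or less transcript per cell lie behind the falls cannot be told apart, since bulk RNA gives no cell counts. An effect of the genotype remains open.

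Lower neuronal transcripts in ob/ob were seen in Npy, Vip, Prph and 6 further neuronal genes, whose median stayed at -1.96 with the 10 most abundant genes left out of the scaling, which argues against scaling. In a second list of ganglion neuron genes, which had not shown the pattern, the median log2 ratio of group means over 18 genes was -1.25, with 15 lower, in line with fewer ganglion neurons in the ob/ob preparations. The most abundant of them with a fall were Th (16.96 ± 1.85 against 24.7 ± 5.32 FPKM), Tubb3 (10.2 ± 1.99 against 21.98 ± 3.49) and Ret (13.2 ± 1.81 against 20.5 ± 2.75; SD, n = 4 each), genes that islet endocrine cells are also known to express, while Phox2a was at 0.145 ± 0.114 against 1.79 ± 0.385. Fewer non-endocrine cells of every kind would lower endothelial markers too, and their median was -0.07, but 2 of 3 Schwann cell, 5 of 16 fibroblast, stellate cell and pericyte (2 rose) and 2 of 3 adipocyte markers fell, so fewer cells of some of these kinds remain open. Whether this reflects the islets of ob/ob mice or their dissection was not tested.

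For higher Reg2, Reg3a, Reg3g and Prss1 in ob/ob, the mean log2 value of the other acinar genes in the highest ob/ob library exceeded that in the lowest ob/+ library by 0.788, below the smallest of the 4 changes (3.18). The lowest ob/ob ratio of Prss1 to its abundant paralog Prss2 was 12.4 times the highest ob/+ ratio, so more acinar RNA does not give the rises, nor does a constant share of Prss2 reads that of Prss1, while a share that differs between the genotypes remains open. DNA of the strain of origin of the ob mutation may remain around Lep, 12.4 Mb from Prss1 and 49.3 Mb or more from the Reg genes: 15.6% of 32 genes within 5 Mb were called, against 18.9% elsewhere (one-sided Fisher's exact p = 0.748), 22.6% of 133 within 20 Mb (0.162), 25.7% of 245 within 50 Mb (0.00459) and 24.0% of 563 on chromosome 6 (0.00114), and for changes of log2 1 or more these p-values were 0.553, 0.0478, 3.91e-05 and 0.000791. Without 16 Reg and trypsin-like genes, among them the 4 that had raised the question, the p-values, across genes, which are not independent replicates, were 0.746, 0.368, 0.0281 and 0.00480 for all calls and 0.543, 0.802, 0.0513 and 0.0710 for changes of log2 1 or more. Such DNA, a change within acinar cells, which was not tested, and an effect of the genotype itself remain open.

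Of the 35 splits of the 8 libraries into 4 and 4, only the real one gave as many as 2208 changed genes. That share, 1 of 35, is the lowest that the splits allow. The highest other split, ob/+ 1, 2 and 3 with ob/ob 3 against the rest, gave 2144, which points to a structure of the samples: it separates libraries with a median log2 value of 3.17 or more from those at 3.08 or less. With the deposited scaling the number of calls therefore does not by itself set the genotype apart from that structure. With median centring the real split gave 3429 genes and no other split more than 1. For the number of called lists, 14 in the real split, 2 of the 35 splits gave as many, the highest other 15, and with median centring, 9 in the real split, 11 of the 35 gave as many, the highest other 15, so chance cannot be excluded.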
